A study of Homo sapiens with 6 samples.

How the data were processed

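Total RNA from HCT116 cells, an established human colon cancer line, was sequenced in 6 libraries: 3 from cells infected with a hairpin vector against TRF2 (shTRF2) and 3 from cells with a control hairpin (shControl). Per the labels' protocols, ribosomal RNA was removed, libraries were made with a strand-preserving total RNA kit and read in paired-end mode at 75 bp. The deposited values were whole read counts per Ensembl gene, 1 table per library with 60675 features, not normalised. Per the submitters' processing notes, FastQC 0.10.1, cutadapt 1.9.1, STAR 2.6.1, featureCounts 1.6.3 and DESeq2 were used with the GRCh38 (hg38) build; the annotation release, the strand setting and other parameters are not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical copies may therefore be split or left out differently than assumed, which can bear on ribosomal protein genes, mitochondrial genes and histones among others.

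Gene names, positions and 3′ UTR sequences came from GENCODE release 29 on GRCh38, which matched 57055 of the 60675 identifiers; the others held at most 0.127% of a library's counts. Samples were grouped by their titles. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No pair of libraries held identical values. Within groups, the chi-square per degree of freedom of pairs lay between 7.41 and 11.71 in shTRF2 and between 17.84 and 35.9 in shControl. Every pair thus differed by more than sampling noise, and all 6 libraries counted as replicates. By this measure the controls differed more among themselves than the shTRF2 libraries.

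Library totals ranged from 16315767 to 43274415 counts. Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 18998. Counts were scaled by the trimmed mean of M values and tested with edgeR's robust quasi-likelihood F test without a block, in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold for a call. The standard error of a log2 fold change was its size divided by the square root of F. Levels are CPM values (counts scaled to a common library size) computed from the deposited counts with the scaled library sizes. In counts simulated from these libraries over 18302 genes, the test recovered 62.7% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 93.9% of those changed 4-fold, and 8.8% of its calls were unchanged genes. The simulation left 18102 genes unchanged, drew the changed ones from genes above a minimum level and held no GC trend. These rates may therefore differ in the real data.

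The 29 gene lists held 572 members, of which 3 could not be matched to an identifier. Lists with at least 3 tested members (27) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with camera using an estimated correlation, and with fry. Genes named in the text were TERF2 and S100A10, the 10 largest rises and 10 largest falls among calls with a mean of at least 5 CPM, groups that did not overlap and a name that is not a clone name, and up to 4 members of each list with the smallest p. Any other gene named was chosen after its values were seen. Some results that this rule covers are not reported here.

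For microRNA sites, the longest annotated 3′ UTR of each tested protein-coding gene was searched for the heptamer TGAATGT, the match to positions 2 to 8 of miR-181a-5p; genes without an annotated 3′ UTR were not searched. Medians of the log2 fold change of genes with and without a site were compared with a two-sided permutation test of 100000 draws within 10 bins of UTR length, beside 50 heptamers of the same bases in another order. These tests run across genes, which are not independent replicates. Distance to a chromosome end was measured from the first base of the chromosome or from the end of its last annotated gene, and calls within 2 Mb were compared with all others by Fisher's exact test. A scan of all heptamers in the same UTRs, chosen after the data were seen, scored the mean log2 fold change of genes holding each heptamer after a fit on UTR length and GC content, over the 15985 heptamers found in at least 100 genes. It was repeated in 20 random splits of the genes, picking the heptamer in one part and scoring it in the other, with base and dinucleotide shares of the UTR also in the fit.

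The gene lists, tests and most alternatives were fixed before the data were examined: other scalings, DESeq2 1.42.0 and limma-voom, other filters, the replicate number as a block, leaving out each library, stricter thresholds and other site or distance definitions. A correction for GC content and transcript length, shTRF2 library 1 alone against the controls, leaving out genes with one heptamer, and strata of GC content and expression were added later. MicroRNA levels were not analysed here.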

Results

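The libraries held 28920091, 43274415 and 16315767 counts in shTRF2 replicates 1 to 3 and 30453484, 29522906 and 32272879 in shControl replicates 1 to 3. Features with at least 1 count numbered 28848, 25104 and 25489 in shTRF2 and 29641, 28592 and 27566 in shControl. At the lowest depth, shTRF2 replicates 2 and 3 would show 24075 and 25489 features, below the 26114 to 28076 of the controls and the 27201 of shTRF2 replicate 1.

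The series asks how silencing TRF2 changes RNA levels in colon cancer cells, and its title names miR-181a-5p and S100A10 as parts of one axis with TRF2. TERF2 (ENSG00000132604; chromosome 16, 69355561 to 69408571, minus strand, GRCh38), the gene for the telomere-binding shelterin protein TRF2, was lower in every shTRF2 library. Its level was 18.9 ± 1.83 CPM (SD, n = 3) in shTRF2 and 63.9 ± 6.14 CPM in shControl, a log2 fold change of −1.76 ± 0.12 (SE; edgeR adjusted p = 9.69e-08). The annotation places another protein-coding gene over part of TERF2 on the same strand, and reads in the overlap may have been left out of both. S100A10 (ENSG00000197747; chromosome 1, 151982915 to 151994390, minus strand), which encodes the light chain of the annexin A2 heterotetramer that binds plasminogen at the cell surface, fell from 79.2 ± 12.8 CPM to 31.9 ± 1.59 CPM (n = 3 each). Its log2 fold change was −1.31 ± 0.12 (edgeR adjusted p = 3.15e-06). ANXA2, its binding partner, stood at 856 ± 12.4 CPM in shTRF2 and 873 ± 47.8 CPM in shControl, with a log2 fold change of −0.03 (edgeR adjusted p = 0.912); it was named after its values were seen.

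**Figure D1:**
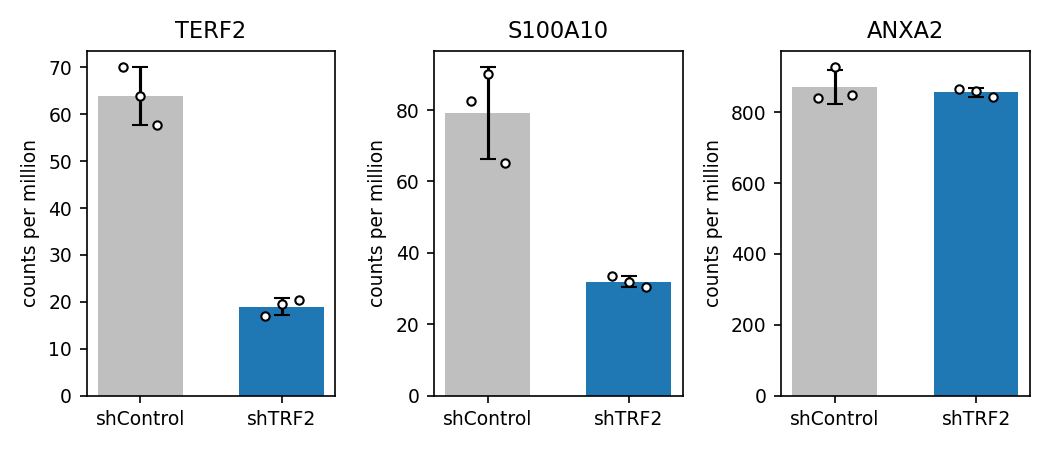
Levels of TERF2, S100A10 and ANXA2 in CPM (vertical axes start at 0) in shControl and shTRF2 cells; bars are means, error bars are SDs and circles are the 3 libraries of each group. For TERF2 and S100A10 every shTRF2 library lies below every shControl library, and for ANXA2 the groups overlap.

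Of 18998 genes tested, 667 were higher and 584 lower in shTRF2, 1251 in all or 6.58%. A change of 2-fold or more was called for 135 genes upward and 91 downward. The groups did not overlap for 24.3% of tested genes, where chance gives 10%. PKIB, an inhibitor of protein kinase A, showed the largest rise among the named genes, from 3.16 ± 0.43 to 38.8 ± 0.95 CPM (log2 fold change 3.62 ± 0.15, edgeR adjusted p = 2.13e-10, n = 3). TMEM200A rose from 7.32 ± 0.91 to 70.2 ± 0.40 CPM (3.26 ± 0.12, edgeR adjusted p = 1.59e-10). The other large rises were in the laminin chain LAMA4 (log2 fold change 2.40), the acyl-CoA synthetase ACSL5 (2.37), the G-protein regulator RGS5 (2.25), KIAA0040 (2.14), the protease inhibitor SERPINE2 (2.14), the ecto-nucleotidase NT5E (2.02), SEMA3D (1.92) and the metalloprotease ADAM19 (1.89). THBS1, which encodes the matrix protein thrombospondin 1, showed the deepest fall among the named genes with a mean of at least 5 CPM, from 87.7 ± 19.7 to 22.6 ± 2.51 CPM (−1.96 ± 0.15, edgeR adjusted p = 5.15e-07). After TERF2 came HECW1 (−1.57), PALM3 (−1.56), SUSD2 (−1.47), the heparan sulfate sulfatase SULF2 (−1.46), the calcium channel subunit ORAI1 (−1.40), KIAA0319 (−1.39), the TGF-beta inhibitor SMAD7 (−1.39) and the keratin KRT80 (−1.36). The count of calls ranged from 543 without shControl replicate 2 to 2123 without shControl replicate 3, was 640, 699 and 769 without shTRF2 replicates 1, 2 and 3, and was 252 with shTRF2 replicate 1 alone against the controls, where the spread comes from the 3 controls and the lone library is assumed to vary like them, so that this count does not show how stable the calls are.

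Genes low in GC tended to be higher in shTRF2. In the fifth of genes with the lowest GC content the median log2 fold change was 0.07, with 231 calls upward and 111 downward, and in the fifth with the highest it was −0.10, with 26 and 123. Libraries of one group also differed in this trend: across genes, which are not independent replicates, the rank correlation of a library's deviation with GC content was 0.014, −0.289 and 0.015 in shTRF2 and 0.21, 0.285 and −0.219 in shControl. With GC content and transcript length corrected for, 817 genes were higher and 907 lower, so that downward calls outnumbered upward ones.

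Among the shelterin genes, TERF2 was the 1 called of 6 tested; TERF2IP had a log2 fold change of 0.29 (edgeR adjusted p = 0.139), ACD 0.09 and TERF1 −0.07. Of 15 genes of telomerase and telomere replication, 1 was called: STN1, a subunit of the CST complex that supports lagging-strand synthesis at telomeres, rose from 25.7 ± 2.13 to 59.4 ± 1.61 CPM (1.21, edgeR adjusted p = 2.11e-06, n = 3). NAF1, PARN and DCLRE1B had log2 fold changes of 0.24, 0.14 and 0.18 and were not called. Neither list was called with camera (adjusted p = 0.783 and 0.342), while fry called both (adjusted p = 0.0341, downward, and 0.0324, upward), and the shelterin median was above 0 where its mean was below. The shelterin list holds TERF2, the silenced gene, and STN1 was the 1 call in the other list. Since fry was not run without these genes, its calls do not show a shift of the other members.

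Of 18 S100 and annexin genes tested, 2 were higher and 3 lower. ANXA5 (0.64, edgeR adjusted p = 0.000311) and ANXA1 (0.52, adjusted p = 0.00157) rose, and S100A4 (−0.90, adjusted p = 0.00133) fell with S100A10. The list as a whole was not called (camera adjusted p = 0.386). Among 11 genes of plasminogen activation 2 were higher, SERPINE2 and the urokinase receptor gene PLAUR (0.64, edgeR adjusted p = 0.0077), and S100A10 was lower; MMP14 had a log2 fold change of 0.45 and was not called (adjusted p = 0.228 with camera and 0.0343 with fry for the list). PLAUR was not called without shTRF2 replicate 1 (adjusted p = 0.0756).

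Of 24 interferon-stimulated genes tested, 11 were higher, 0 lower and 13 not called (14 and 0 adjusted over the list alone), with a median log2 fold change of 0.63 and a camera adjusted p of 4.93e-10; the adjusted p was 0.131 with an estimated correlation and 0.00334 with fry. OAS3, an antiviral oligoadenylate synthetase, rose from 47.5 ± 3.31 to 75.1 ± 2.78 CPM (0.66, edgeR adjusted p = 0.000465, n = 3). The RNA sensor gene IFIH1 (0.98) and PARP9 (0.84) rose with it. Of 17 genes of NF-kB signalling and inflammatory secretion, BIRC3 (1.18) and NFKB1 (0.38) were higher and none lower (camera adjusted p = 0.0436; adjusted p = 0.726 with an estimated correlation and 0.144 with fry), and 4 were higher adjusted over the list alone. IL18 (0.39) and TNFAIP3 (0.72) were not called. NFKB1 lost its call without each library other than shControl replicate 3, and the list lost its call without each shTRF2 library and without shControl replicate 3.

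Of 28 p53 target genes tested, 8 were lower, 0 higher and 20 not called (16 lower and 1 higher adjusted over the list alone), with a median of −0.32 and a camera adjusted p of 2.03e-05; the adjusted p was 0.131 with an estimated correlation and 0.00324 with fry, and 5 members had a log2 fold change above 0. TP53INP1 went from 74.6 ± 9.17 to 39.9 ± 5.74 CPM (−0.91, edgeR adjusted p = 0.00023, n = 3). ZMAT3 (−0.73), the p53 ubiquitin ligase gene MDM2 (−0.54) and GDF15 (−0.94) were also lower. CDKN1A, the cell cycle inhibitor p21 and a member of the list of reported TRF2 and angiogenic targets too, was lower (−0.57, edgeR adjusted p = 0.00318). In that list of 9 tested genes SULF2 and CDKN1A were lower and 0 higher, while HPSE (−0.44) and VCAN (−0.30) were not called (camera adjusted p = 0.0134; adjusted p = 0.259 with an estimated correlation and 0.00141 with fry); 4 were lower adjusted over the list alone. With shTRF2 library 1 alone, where the controls supply the spread, the camera adjusted p was 0.0606, which with 1 library in an arm does not show that the call is unstable.

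In the list of epithelial-mesenchymal and adhesion genes, 7 of 28 were higher, 2 lower and 19 not called (camera adjusted p = 0.0313; adjusted p = 0.259 with an estimated correlation and 0.0201 with fry), or 9 and 2 adjusted over the list alone. The integrin gene ITGA2 rose from 132 ± 6.41 to 225 ± 8.23 CPM (0.77, edgeR adjusted p = 5.35e-05, n = 3), and the integrin genes ITGB1 (0.54) and ITGB4 (0.59) rose with it. The list was not called without shTRF2 replicate 1 or without shControl replicate 3.

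In 4 other lists called by camera, few members were called singly over all genes. Among 13 mitochondrially encoded mRNAs MT-ND6 (0.71) and MT-ND3 (0.74) were higher, 4 adjusted over the list alone (camera adjusted p = 0.0134; adjusted p = 0.891 with an estimated correlation), and both lost their edgeR call with GC content and length corrected for. Of 28 ribosomal protein genes RPL15 (0.38) and RPL10 (0.40) were higher, and 23 had a log2 fold change above 0 (camera adjusted p = 0.0416; adjusted p = 0.891 with an estimated correlation). Of 16 replication-dependent histone genes H4C8 was lower, and 7 were lower adjusted over the list alone (−0.53 for H4C8; camera adjusted p = 0.0232 and 0.891 with an estimated correlation as adjusted p). Of 24 genes of the unfolded protein and integrated stress response, HERPUD1 (−0.47) and NUPR1 (−2.36) were lower. NUPR1 stood near the floor, at 0.16 ± 0.10 CPM in shTRF2 and 0.94 ± 0.45 CPM in shControl. Adjusted over the list alone, 5 were lower and 1 higher (camera adjusted p = 0.0436, and 0.821 as adjusted p with an estimated correlation). Each of these 4 lists lost its call without at least 1 library, and fry called none of them (adjusted p = 0.331, 0.434, 0.331 and 0.144 in this order).

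In the remaining lists camera called no direction. Of 16 Wnt targets DKK1 was higher (0.43) and BMP4 (−0.54) and EPHB2 (−0.60) lower. RPA1 was the 1 lower of 26 DNA damage and repair genes (−0.47), CCNE1 the 1 lower of 26 DNA replication and S phase genes (−0.56), and SLC2A1 the 1 lower of 23 hypoxia and glycolysis genes (−0.61). Of 25 G2/M genes edgeR called 0; MKI67 had a log2 fold change of −0.55 (adjusted p = 0.105). The intestinal gene CA2 was lower (−0.89) among 6 tested, KCNQ1OT1 (−0.73) among 8 nuclear and structural RNAs, and B2M (0.69) and GUSB (0.50) were higher among 15 housekeeping genes. Among markers of other cell types, edgeR called 1 of 6 fibroblast markers (COL3A1, 1.70 against 0.33 CPM) and 0 of 5 endothelial, 5 neuronal, 2 leukocyte and 1 liver markers. Some of these stood well above the others, with means of 16.7 CPM in shTRF2 and 14.5 CPM in shControl for MAP2, 12.5 and 10.8 CPM for COL1A1 and 9.56 and 8.47 CPM for EGFL7, named after their values were seen. Median, mean and camera direction differed in sign for the DNA damage, fibroblast, endothelial, neuronal, intestinal, microRNA machinery and reported miR-181 target lists. The calls of DKK1, BMP4, EPHB2, RPA1, CCNE1, CA2, GUSB, COL3A1, DICER1, H4C8, HERPUD1, NUPR1, RPL15, RPL10, MT-ND6 and MT-ND3 were each lost without at least 1 library.

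To address the microRNA named in the title, genes were split by a match to miR-181a-5p. Among 13303 tested genes with an annotated 3′ UTR, 2801 held a match and had a median log2 fold change of 0.001, against −0.014 for 10502 genes without. The difference of 0.0149 was not larger than UTR length and chance give (two-sided permutation p = 0.126), and camera called no shift (p = 0.59). With the shortest annotated 3′ UTR of each gene the difference was 0.0178 (permutation p = 0.0285). Without shTRF2 replicate 1 the difference was 0.0271 (permutation p = 0.0139) and without shControl replicate 3 it was 0.048 (permutation p = 0.00107), while without shTRF2 replicate 2 and without shControl replicate 2 it was −0.00942 and −0.0138. Without regard to UTR length, genes with a match were called more often in both directions: 6.46% against 3.95% were higher (odds ratio 1.68, two-sided Fisher's exact p = 4.38e-08) and 5.14% against 3.76% lower (1.39, Fisher's exact p = 0.00143). Over 50 other orders of the same bases these odds ratios ran from 1.28 to 2.08 for higher and from 1.03 to 1.73 for lower. Each of the 50 other orders of the same bases gave a difference, less that of UTR length, of 0.011 or more, above the 0.00899 of the miR-181a-5p match. The 2 annotated 3′ UTRs of S100A10, of 245 and 248 bases, held 0 copies of TGAATGT or of its last 6 bases. Other pairings were not searched. MIR181A1HG, a long RNA that hosts a miR-181a gene, rose from 6.91 ± 0.41 to 14.1 ± 1.27 CPM (1.03, edgeR adjusted p = 0.000562, n = 3). Among 13 genes of microRNA hosts and machinery DICER1 was also higher (0.37) and TNRC6A lower (−0.47). Of 25 reported miR-181 family targets S100A10 was lower and the phosphatase gene DUSP6 higher (0.83, edgeR adjusted p = 1.54e-05). PLAG1 (1.01) and PRKCD (−0.36) were not called. The gene lists drew in part on genes named in the series title, S100A10 among them. Its fall is therefore not independent evidence that miR-181 targets fell.

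Since TRF2 binds chromosome ends, genes were also compared by distance to them. Of 1279 genes within 2 Mb of an end 38 were called (2.97%), 10 higher and 28 lower, against 6.87% of 17516 genes elsewhere (odds ratio 0.415, two-sided Fisher's exact p = 3.01e-09, across genes). The genes near the ends were richer in GC, with medians of 57.7% and 47%. Within 25 strata of GC content and expression the odds ratio was 0.509, and with GC content and length corrected for it was 0.429. It thus stayed below 1 with GC content allowed for. Camera gave a downward p of 0.0488 for genes within 2 Mb, 0.185 within 1 Mb and 0.0275 within 5 Mb. Median log2 fold changes near the ends and elsewhere were −0.0776 and −0.0085, and −0.0262 and −0.0131 with the correction.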

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

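Leaving out libraries, stricter thresholds and added corrections moved the count of calls or lists by over 1.5 times; no cause was tested unless the construction gives it. TERF2 and S100A10 stayed lower and called in all alternatives, with log2 fold changes from −1.83 to −1.68 and −1.43 to −1.21 when 1 library was left out. Leaving out 1 library gave 543 to 2123 calls (286 to 1100 higher, 257 to 1023 lower) and 4 to 8 lists, and a miR-181a-5p site difference from −0.0138 to 0.048, below 0 at −0.00942 without shTRF2 replicate 2 and −0.0138 without shControl replicate 2. Stricter thresholds left 226 calls at a 2-fold change (135 higher, 91 lower) and 567 at an adjusted p under 0.01 (329 higher, 238 lower). A mean of at least 5 CPM gave 5 lists and the estimated correlation 0 (camera; 4 at an unadjusted p under 0.05, and fry called 7, of which 4 were among the 9 of camera and 3 were shelterin, telomerase and plasminogen activation). The site difference passed the threshold with the shortest UTR (0.0178, permutation p = 0.0285) and without shTRF2 replicate 1 (0.0271, permutation p = 0.0139). It also did so without shControl replicate 3 (0.048, permutation p = 0.00107). These tests allowed for UTR length, but not for GC content or the background of other orders of the bases. Of the alternatives added after seeing the data, the GC and length correction gave 907 lower genes, shTRF2 library 1 alone gave 252 calls (167 higher, 85 lower) and 5 lists, with fewer libraries and a spread taken from the controls, and leaving out genes with the heptamer ATAAGCA gave 377 lower genes, with fewer genes tested. The replicate numbers did not pair the libraries: correlations of deviations were 0.039, −0.036 and −0.066, and not every library correlated best with its own number. The replicate block gave 882 calls (474 higher, 408 lower), of which 852 were shared with the unblocked fit, 5 lists, and a site difference of 0.0146. DESeq2 called 1624 genes and limma-voom 1281. The depth of 16315767 counts in shTRF2 replicate 3 may limit what can be called among genes of few counts, which was not tested.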

Other observations

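The tests of heptamers, of GC content on the lists and of the splits were chosen after the results they bear on were seen, and so was the form in which 3′ UTR and coding sequence sites were compared.

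Among genes called lower in shTRF2 and searched for sites, 170 of 539 (31.5%) held the heptamer ATAAGCA in the longest annotated 3′ UTR. Of 1531 tested genes with it 11.1% were lower, against 3.13% of 11772 without (odds ratio 3.86), while 4.64% and 4.46% were higher. The fallen genes with the smallest p that hold it, named after their values were seen, include the E2F partner gene TFDP1 (175 ± 7.73 to 71.8 ± 1.20 CPM, log2 fold change −1.29), THBS1 (−1.96), the actin-capping gene TMOD3 (−0.98), the lamin gene LMNB1 (−0.97), KATNAL1 (−1.05) and CPT1A (−0.90). Of the genes named in the report, the lower ORAI1, SMAD7, RPA1, ZMAT3, HERPUD1 and TNRC6A hold it too, as do RGS5 and DICER1, which were higher, and MAP2, PRKCD and TERF1, which were not called; 5 of 11 searched genes of microRNA hosts and machinery hold it, 1 of them lower. The share called lower was 15% for genes with the heptamer followed by A and 9.21% for the heptamer alone. It was 7.06% for its last 6 bases followed by A, 3.49% for those 6 bases alone and 2.70% without them. These shares and the odds ratio take no account of UTR length. After a fit on UTR length, GC content and coding sequence length, median differences from genes without the 6 bases were −0.185, −0.127, −0.096 and −0.0417 in this order. Their SEs across genes were 0.0212, 0.00997, 0.00782 and 0.00608. After a fit on UTR length and GC content the heptamer scored −10.67, the lowest of the 15985 scanned, against −5.32 for the lowest score in 1000 shuffles of the genes. The median difference of genes with and without the heptamer, less that of UTR length, was also taken in 9 pairs of a shTRF2 and a shControl library. It was below 0 in each, from −0.123 to −0.0321. These pairs share libraries and reuse the data from which the heptamer was picked, so their common sign is not independent support. S100A10 does not carry it in its annotated transcripts, and TERF2 carries it in 4 of 12, in a coding sequence and in 0 of 2 annotated 3′ UTRs.

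UTR length and base composition alone do not explain this: in the 18 of 20 random splits of the genes that picked ATAAGCA, it scored 3.73 to 6.01 below the lowest of 207 orders of its bases that share no 6 bases in a row with it, in the genes left out (SD of those orders at most 1.03). The form of this test was changed after its results were seen: a form that asked for ATAAGCA in all 20 splits was not met, and in a form that scored the picked heptamer the 2 splits that picked TAAGCAA gave gaps of −1.72 and 0.14 to AATAAGC, which shares 6 bases with ATAAGCA. Adding base and dinucleotide shares to the fit moved 0 heptamer scores by over 1, so the comparison rests on the other orders. In the left-out genes of the same 18 splits, genes with a 3′ UTR site were compared with genes with a site in the coding sequence alone. The former lay lower, by −0.138 to −0.0758 (SE 0.0203 for the latter value), the direction that pairing of a short RNA guide predicts. ATAAGCA was picked for a low score in 3′ UTRs, so this direction does not single out a guide. Over all genes, those with the site in the coding sequence alone also lay lower, by −0.0312 (SE 0.0134). A hypothesis is that the hairpin's guide strand may repress genes with a 3′ UTR site through its seed. The hairpin's sequence is not given in the sources used here. An effect of losing TRF2 itself cannot be told apart from repression by the guide, since the labels name 1 silencing condition. Of the 10 splits of the 6 libraries 1 gave a difference as far from 0 (−0.0736 for the real split, at most 0.0512 in size for others), and 10 splits cannot give a share under 0.05.

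The upward call of the interferon-stimulated genes and the downward call of the p53 targets were set against the GC and length trend and against repression at ATAAGCA sites. With the GC and length trend removed, the camera adjusted p was 7.41e-10 for the interferon-stimulated genes and 4.99e-06 for the p53 targets, so the trend does not explain either by itself. Without genes holding ATAAGCA the values were 1.82e-09 and 7.62e-06. Only 1 of 24 and 3 of 28 members hold it, so leaving them out could change little and decides nothing. Both lists lost their camera call in the form that estimates the correlation, while fry called both (adjusted p = 0.00334 and 0.00324). The estimates were 0.063 for the interferon-stimulated genes and 0.014 for the p53 targets, against the preset 0.01. The lists of TRF2 targets and of adhesion genes lost their calls with estimates of −0.084 and −0.01, below the preset. Correlation between members alone therefore does not account for all of the lost calls. Whether the interferon-stimulated genes and p53 targets follow the loss of TRF2, the hairpin or the infection was not tested. Over all other alternatives the adjusted p ranged from 1.06e-10 to 5.21e-07 for the interferon-stimulated genes and from 5.78e-07 to 0.00268 for the p53 targets.

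Of the 10 splits of the 6 libraries 1, the real one, gave as many called genes: 1251, against 0 by edgeR in the others. Those had 180 to 1707 genes at an unadjusted edgeR p under 0.05. Each of them puts shTRF2 and shControl libraries in the same group, so the real difference widens the spread within groups. Few calls are then likely by construction, and 0 is not the count that chance alone would give. For called lists 1 split gave as many, the real one with 9, against 0 to 4 in the others. Groupings that mix the hairpins thus also gave list calls by camera, which bears on lists near the threshold. For the miR-181a-5p sites 5 splits, the real one included, gave a difference, less that of UTR length, as far from 0 as the real 0.00939 (from fewer draws), at most 0.0329 in size for the others. In each case 10 splits are too few for a share under 0.05.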
